A study of Arabidopsis thaliana with 4 samples.

How the data were processed

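Total RNA from Arabidopsis thaliana inflorescences was hybridised to 4 Operon arrays with 2 channels each, per the labels. Every array carried RNA from apetala2 mutant inflorescences in one channel and RNA from wild-type inflorescences in the other, per the labels. APETALA2 is a transcription factor of floral organ identity, and strong mutants are known to lack petals and to form fewer stamens. The labels place apetala2 in channel 1 on sets 1 and 3 and in channel 2 on sets 2 and 4, so the channels were balanced, with 2 arrays each way. The labels name neither the dyes nor the mutant allele, and they do not say whether the 4 sets came from separate plants. The p-values therefore measure only the spread between these 4 arrays, which may be technical.

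The deposited values are log2 ratios of the 2 channels, normalized by the authors as an earlier publication describes, per the labels. The scanner, background correction and filters are not given in the sources used here. Which channel or genotype is the numerator of the ratio is also not given. No signal intensities were used here, so the brightness behind each ratio is unknown and the number of arrays limits the precision. The deposited table held 26933 spots, of which 459 were control spots (424 of them named empty) and 26474 were gene probes.

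The deposited log2 values stop at 6.64 on either side, which is the log2 of a ratio of 100. On every array most spots named empty sat at the upper limit. A value within 0.0001 of the limit was therefore treated as no measured ratio, although the design fixed before the data were examined had kept deposited values as they were. The fits with these values kept are among the alternatives. Control spots were left out of all fits.

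The fixed design asked that sets 2 and 4 be turned in sign if they correlated below 0 with sets 1 and 3 over all probes. With the limit values included every correlation between arrays lay above 0. Among measured ratios those 4 correlations had both signs, and the labelled channels were followed. Positive values in this labelled orientation stand for apetala2 over wild type if channel 1 is the numerator, and for the reverse if channel 2 is. Sets of the same labelled channel correlated below 0. Each comparison is therefore also given with sets 2 and 3 turned, which exchanges the channels of sets 3 and 4. Exchanging those of sets 1 and 2 instead would give the same p-values with every sign reversed. The ratios cannot tell which pair, if either, departs from its labels. That second orientation was chosen after the data had been examined, so its p-values carry no allowance for the choice. The design would have named a likely direction from the anther and pollen lists. None is named, because the allele is not given and the median of the anther list lay near 0 in sets 3 and 4.

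The fit was an intercept in limma 3.58.1 (R 4.3.3), with lmFit and eBayes on probes measured on at least 3 arrays, a two-sided test against 0 and Benjamini-Hochberg adjustment. A probe passed at an adjusted p under 0.05. Errors of fitted means are the moderated standard errors (SE), with n = 4 arrays unless stated. The fit was tested on 2 simulations of 25185 probes, of which 200 were changed. Both took each probe's spread from the real ratios with sets 2 and 3 turned, so they differ only by random draw. On the log2 scale the run signed by the labelled channels recovered 38% of changes of 1 and 70% of changes of 2. It recovered 92% of changes of 3 and 100% of changes of 4. The run with the other signs recovered 22%, 86%, 92% and 92%. Each simulation gave 8 false calls among the unchanged probes. The spread in the labelled orientation was not simulated, so the power behind the labelled counts is unknown.

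Probes were named from the platform annotation supplied with the values, with symbols updated through the TAIR10.1 gene table. Of the gene probes, 5784 had exactly 1 gene, 7497 had several and 13193 are unnamed here. Of the probes with 1 gene, 5756 matched the table. No gene was named from a probe with several. Among 249 genes with exactly 2 measured probes of their own, the probes' mean log2 ratios with sets 2 and 3 turned correlated at r = 0.467 across genes, against 0.0213 after shuffling. Genes are not independent replicates. No coordinates are printed, because the build behind the probe design is not given in the sources used here.

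The rule for the genes named was fixed with the design, and genes named outside it are said to be chosen after their values were seen. The rule took AP2, up to 12 genes per side with the largest mean among passing probes with 1 gene, 4 values and 1 sign, up to 4 members per fixed list, and any member of the floral identity and carpel lists. In the labelled orientation no probe passed, so the 24 genes of the second part come from the other orientation. The 15 fixed lists covered floral identity, carpel and ovule, anther and tapetum, mature pollen, petal growth and cuticle, photosynthesis, jasmonate, flavonoids, glucosinolates, cell cycle, seed and embryo, stress and defence, meristem and polarity, nectary, and reference genes. They held 306 distinct genes, of which 19 had a tested probe of their own. AP2 had none. List tests were also run on probes that list a member among several genes, an alternative added after the coverage was known. Lists of at least 3 probes measured on all 4 arrays were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list's probes move one way on balance.

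Alternatives comprised a channel term, median centring, scale normalization, a complete-values filter, a size threshold of 1, robust moderation and no moderation. Others were averaging sets 1 with 2 and 3 with 4 (pairs that the labels do not state), array weights, and leaving out each array. The channel term follows the signs of the orientation fitted, so in both orientations it takes up the mean of the unturned ratios. The values with limit ratios kept, and all 8 patterns of signs over the 4 arrays, were added later. Intervals of correlations are 95% bootstrap intervals over probes from 1000 resamples.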

Results

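The arrays compared transcript levels in apetala2 and wild-type inflorescences of Arabidopsis thaliana, the shoots that carry flower buds and open flowers. The question the pairing of genotypes on every array addresses is which transcripts differ in abundance when APETALA2, a regulator of sepal and petal identity, is mutated. The 4 arrays, called sets 1 to 4, form 1 group, and each gives 1 log2 ratio per probe. Whether they are independent replicates is not stated in the labels. Measured ratios of gene probes numbered 25778 on set 1, 25841 on set 2, 25747 on set 3 and 25741 on set 4. Their medians on the log2 scale were 0.0588, -0.0143, 0.00362 and 0.0295 on sets 1 to 4, and their standard deviations over probes 0.690, 0.607, 0.615 and 0.669.

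Spots named empty did not give ratios near 0. Of the spots named empty that had a value, 405 to 417 per array, 62.8% sat at the upper limit of the scale on set 1, 71.1% on set 2, 86.6% on set 3 and 87.0% on set 4. Of the gene probes, between 2.05% and 2.64% did so per array, and between 8 and 32 sat at the lower limit. On all 4 arrays 272 gene probes were at a limit, 271 of them at the upper limit throughout. These values were left out, which left 25777 probes with a measured ratio on at least 3 arrays and 25185 with one on all 4.

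**Figure D1:**
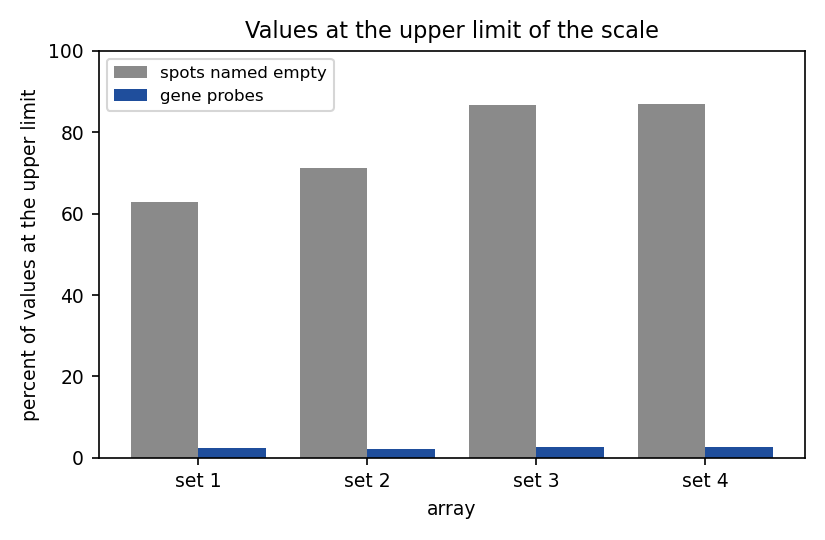
Bars give the percent of values at the upper limit of the log2 scale on each of the 4 arrays, for spots named empty with a value (grey) and for gene probes (blue). Empty spots reach 62.8% to 87.0%, gene probes 2.05% to 2.64%.

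The sets did not run in the directions that their labelled channels give. Across measured probes, deposited ratios of sets 1 and 2 correlated at r = -0.479 (95% bootstrap interval -0.500 to -0.459, Spearman -0.340) and those of sets 3 and 4 at r = -0.474 (-0.501 to -0.445, Spearman -0.357), as channel-swapped arrays with unturned ratios would. Sets 1 and 3, which share the labelled channel of apetala2, correlated at r = -0.227 (-0.248 to -0.206, Spearman -0.0684), and sets 2 and 4, which also share it, at r = -0.119 (-0.137 to -0.0995, Spearman -0.00872). Sets 1 and 4 correlated at r = 0.313 and sets 2 and 3 at r = 0.307, although their labelled channels are opposite. These correlations are across probes, which are not independent replicates. Among 346 probes beyond 1 in size on all 4 arrays, 298 were negative on sets 1 and 4 and positive on sets 2 and 3, and 26 had the mirror image of that pattern. The labelled channels were followed by 13 and 2 such probes. Of the sum of squares over probes measured on all 4 arrays, 50.3% lay in the contrast of sets 1 and 4 with sets 2 and 3 and 24.8% in the labelled contrast. The mean of the unturned ratios held 15.5%, and the contrast of sets 1 and 2 with sets 3 and 4 held 9.45%. The labelled share is thus near an equal split over these 4 contrasts.

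**Figure D2:**
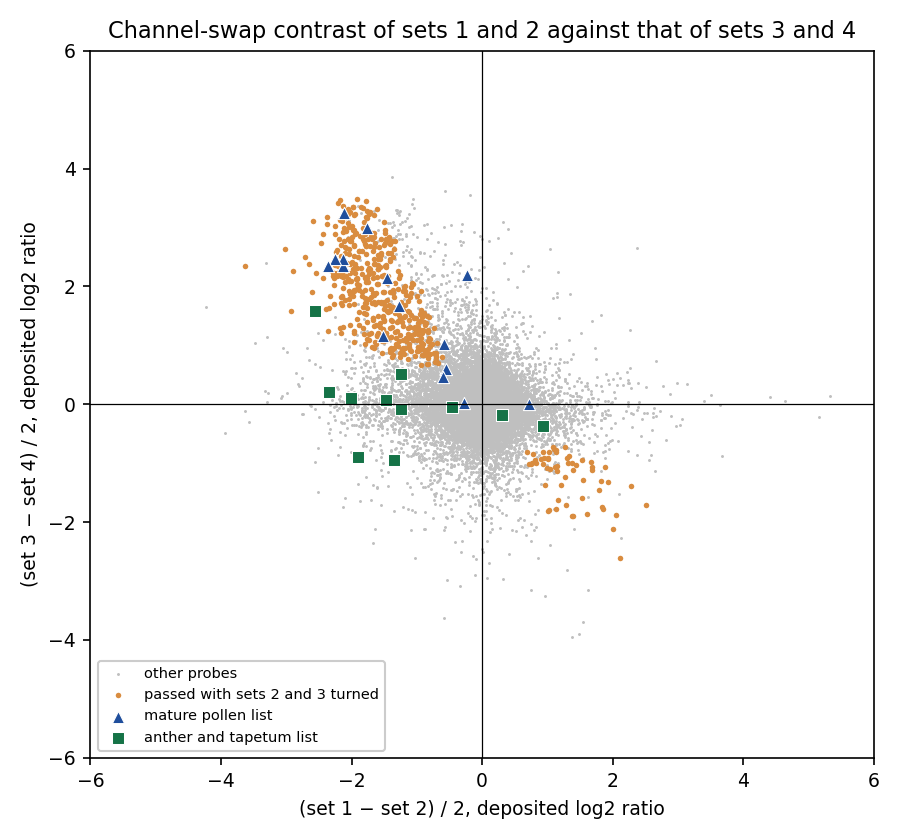
Each point is a probe measured on all 4 arrays, placed by the contrast of set 1 with set 2 (x axis) and of set 3 with set 4 (y axis), each as the difference of deposited log2 ratios divided by 2. Probes that follow the labelled channels alike would lie on the rising diagonal; the 528 probes that passed with sets 2 and 3 turned (orange, drawn where all 4 values exist) and 93.3% of the mature pollen probes (blue triangles) have opposite signs on the axes, and most anther and tapetum probes (green squares) lie left of 0.

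The overall direction of the ratio is unsettled for the same reason, and no gene is called higher or lower in a genotype as a fact. Values with sets 2 and 3 turned are given by side, negative where sets 1 and 4 are negative. Probes of the mature pollen and anther lists lay mostly on the negative side. The anther list lay there in sets 1 and 2, with a median of -1.36, and near 0 in sets 3 and 4, with a median of 0.0464.

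No single probe passed in the labelled orientation, and neither list with at least 3 probes of 1 gene passed a set test. The anther and tapetum list had a camera adjusted p of 0.0971 over 5 such probes (adjusted p = 0.447 with an estimated correlation) and the photosynthesis list one of 0.153 over 4, with a median of 0.14. Without set 2 the photosynthesis median was 0.33 (camera adjusted p = 0.00297, adjusted p = 0.231 with an estimated correlation, fry adjusted p = 0.0236). Of 25777 probes, 0 had an adjusted p under 0.05 in limma, 1689 had an unadjusted p under 0.05 against 1289 expected by chance, and the lowest adjusted p was 0.258. A test without moderation also passed 0 probes, with 1780 at an unadjusted p under 0.05. AP2 itself had no probe that lists it. Of the genes named by list, UGT78D1, a flavonol rhamnosyltransferase, had a mean log2 ratio of -0.81 ± 0.29 (SE, n = 4, limma adjusted p = 0.760). ATA27, an anther gene of the beta-glucosidase family, had -1.07 ± 0.57 (SE, n = 4) and ATA20, another anther gene, -0.95 ± 0.51 (SE, n = 4), each with a limma adjusted p of 0.761. The second probe of ATA27 had 0.07 ± 0.18 and that of ATA20 -0.66 ± 0.30 (SE, n = 4). PRK, the phosphoribulokinase of the Calvin cycle, had 0.60 ± 0.30 (SE, n = 4, limma adjusted p = 0.760). When probes that list a member among several genes were included, a definition added after the coverage was known, the anther and tapetum list had a median of -0.66 over 11 probes, and 9 of them lay below 0. Its median was -0.29, -0.43, -0.98 and -0.98 without sets 1, 2, 3 and 4. The camera test gave this list an adjusted p of 0.000713 at the preset correlation and an adjusted p = 0.670 with an estimated correlation. With fry the list had an adjusted p of 0.267. None of its probes passed over all probes, and 2 passed when adjusted over the list alone. Probes listing a carpel or ovule gene had a median of 0.03 over 12 probes and those listing a pollen gene 0.17 over 15, with camera adjusted p of 0.883 and 0.692. The pollen median changed sign between arrays left out, with 0.89 and 0.76 without sets 1 and 2 and -0.21 and -0.29 without sets 3 and 4, and the carpel median was -0.10, 0.10, 0.13 and 0.13 without sets 1, 2, 3 and 4. Leaving out an array changed 3 further calls among these lists besides those of photosynthesis. The pollen list had an adjusted p of 0.0277 and the seed and embryo list one of 0.0442 without set 1, and the anther members with a probe of their own one of 0.0242 without set 3. With an estimated correlation these calls were lost (adjusted p = 0.620, 0.620 and 0.372).

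Of 17 probes that list a mature pollen gene, 8 passed with sets 2 and 3 turned, all negative, and each of the 8 lists several genes and some list the same ones (camera adjusted p = 2.49e-16, adjusted p = 0.160 with an estimated correlation). RALFL25 on the negative side and CES on the positive side, with 6.31-fold and 4.33-fold differences, were among the genes that differed most. In all, 528 probes passed, 470 on the negative side and 58 on the positive side. All 528 had the same sign on every array that measured them. The median change was -1.78 on the log2 scale on the negative side and 1.205 on the positive side. The 470 negative probes comprised 72 with 1 gene, 173 with several and 225 unnamed here, and the 58 positive probes 12, 16 and 30. The count fell to 94 without set 1, 117 without set 3 and 116 without set 4, and was 441 without set 2. The positive side moved more, to 6, 25, 6 and 8 probes without sets 1, 2, 3 and 4 and to 34 with the channel term. On both sides the count was 0 when sets 1 and 2 and sets 3 and 4 were averaged to 2 replicates, with 1934 probes at an unadjusted p under 0.05. The 24 genes named below then had limma adjusted p from 0.138 to 0.3745, so their calls rest on counting 4 separate arrays.

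The negative side was led by AT3G26860, with a mean of -2.996 ± 0.483 on the log2 scale (SE, n = 4, limma adjusted p = 0.0452), a 7.98-fold difference. RALFL25, of the family of small secreted RALF signalling peptides, had -2.66 ± 0.34 (SE, n = 4, limma adjusted p = 0.0244), and its deposited ratios were -2.49 and -3.19 on sets 1 and 4 and 1.45 and 3.50 on sets 2 and 3. AT1G13670 had -2.59 ± 0.36 and AT1G35490 -2.52 ± 0.26 (SE, n = 4). AT1G13970, AT3G21570, AT5G62750, AT3G62710, AT5G50830, AT3G52620, AT4G03620 and AT1G15415 followed, with means from -2.51 to -2.33. AT3G62710 has a second probe of its own, which gave -2.36 ± 0.39 (SE, n = 4, limma adjusted p = 0.0505). With the labelled channels the same 12 genes had means between -0.64 and 0.86, none of which passed (lowest limma adjusted p 0.885). Their selection for 1 sign on all 4 arrays with sets 2 and 3 turned largely fixed this in advance.

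The positive side was led by AT5G53710, with 2.36 ± 0.25 (SE, n = 4, limma adjusted p = 0.0152), and by CES, a basic helix-loop-helix transcription factor, with 2.12 ± 0.20 (SE, n = 4, limma adjusted p = 0.0116), a 4.33-fold difference. AT3G58550 had 1.74 ± 0.19 and AT1G51030 1.64 ± 0.16 (SE, n = 4). AT2G31990, AT3G27870, AT5G53730, AT5G12930, AT5G11360, ALDH3F1, AT1G16960 and TRM34 had means from 1.16 to 0.75. ALDH3F1, an aldehyde dehydrogenase, had 0.88 ± 0.13, and TRM34, of the family of TONNEAU1-recruiting proteins, 0.75 ± 0.12 (SE, n = 4). All 12 genes with a passing probe of their own on this side are thus named. With the labelled channels they had means between -0.25 and 0.40, none of which passed (lowest limma adjusted p 0.949). For these genes too the selection largely fixed this in advance.

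**Figure D3:**
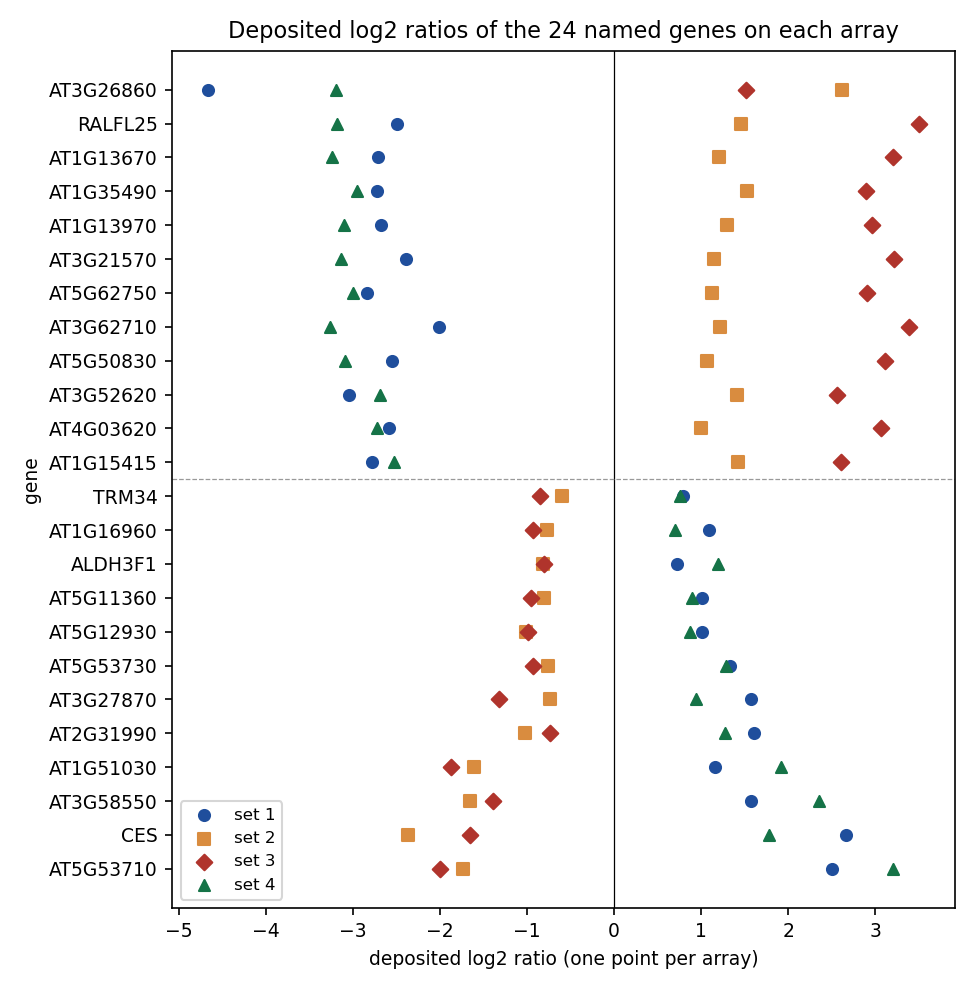
Deposited log2 ratios (x axis) of the 24 genes named by the fixed rule (y axis), 1 point per array; the dashed line parts the 12 negative from the 12 positive genes. Sets 1 and 4 lie on one side of 0 and sets 2 and 3 on the other for every gene, and set 2 lies nearest to 0 for all negative genes but AT3G26860.

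Among the fixed lists, mature pollen probes moved most with sets 2 and 3 turned. This and the following set tests use the added definition by probes that list a member. Over probes with 1 gene, the anther and tapetum list had a camera adjusted p of 0.135 (5 probes, 0.0375 without set 4) and the photosynthesis list one of 0.244 (4 probes, 0.0137 without set 1). With an estimated correlation the calls without an array were lost (adjusted p = 0.402 without set 4 and adjusted p = 0.222 without set 1). With fry the anther list had an adjusted p of 0.236 without set 4 and the photosynthesis list one of 0.0219 without set 1. Of 17 probes listing a pollen gene, 8 passed, all on the negative side. Several of the 8 list the same member, so they stand for few of the list's 35 genes. Of the 17 probes, 16 lay below 0, and 14 passed when adjusted over the list alone. The median of the 15 with all values was -1.47 (camera adjusted p = 2.49e-16 at the preset correlation, adjusted p = 0.160 with an estimated correlation, fry adjusted p = 0.00662). The camera call at the preset correlation held without any 1 array, whereas the fry call was lost without set 1 (adjusted p = 0.0787), set 3 (adjusted p = 0.0907) and set 4 (adjusted p = 0.0529). The pollen gene with a probe of its own, TUA1, an alpha-tubulin, had -0.53 ± 0.12 (SE, n = 4, limma adjusted p = 0.121) and so did not pass over all probes.

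Anther and tapetum probes gave a median of -0.59 over 11 probes, of which 1 passed, on the negative side, and 9 lay below 0 (camera adjusted p = 0.0200, adjusted p = 0.702 with an estimated correlation). The fry adjusted p was 0.422. Adjusted over the list alone 1 of the 11 passed. Among the 5 members with a probe of their own, none passed over all probes and 2 passed when adjusted over the list alone. RPG1, a sugar transporter of the SWEET family that pollen wall formation requires, had -0.87 ± 0.25, and EMS1, the receptor kinase that specifies the tapetum, 0.65 ± 0.20 (SE, n = 4), each with a limma adjusted p above 0.2 over all probes and of 0.0496 over the list. ATA27 had -1.27 ± 0.47 and its second probe 0.24 ± 0.15 (SE, n = 4), so the probes of this gene disagreed. ATA20 had -1.06 ± 0.44 and its second probe -0.59 ± 0.31 (SE, n = 4). The camera call was lost without set 1 (adjusted p = 0.148) and without set 2 (adjusted p = 0.179), and the median was -0.40, -0.33, -0.89 and -0.93 without sets 1, 2, 3 and 4.

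Carpel and ovule probes had a median of 0.16 over 12 probes, of which 1 passed, on the positive side (camera adjusted p = 0.0403, adjusted p = 0.702 with an estimated correlation). The fry adjusted p was 0.149. When adjusted over the list alone 4 passed. The 2 with the smallest p list the same 2 genes (means 1.29 and 1.06), and 1 of the 4, that of INO, lay on the negative side. The camera call was lost without set 1, where the median was 0.05 (adjusted p = 0.128), and without set 3 (adjusted p = 0.0931). INO, a YABBY gene of the outer integument and the 1 member with a probe of its own, had -0.66 ± 0.19 (SE, n = 4, limma adjusted p = 0.205) on the probe that stands for it and -0.04 and -0.08 on its other probes. SEU, a transcriptional co-repressor of AGAMOUS, had 0.11 ± 0.13 (SE, n = 4, limma adjusted p = 0.753). Of 7 probes listing a floral identity gene none passed. That list held 27 genes, of which only SEU had a tested probe of its own. The other probes list few of the rest, so this count does not speak for floral identity genes at large.

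Stress and defence probes, included as a sign of the condition of the plants, numbered 5, of which 2 passed on the negative side, beside the pollen probes (camera adjusted p = 0.0200, adjusted p = 0.702 with an estimated correlation, adjusted p = 0.226 without set 2). The 2 passing probes list the same member (means -1.07 and -1.18), each beside another gene. A further probe listing that member had -0.16 ± 0.46 (SE, n = 4, limma adjusted p = 0.9065), so its probes disagreed. The remaining probes list a different member and had means of -0.28 and 0.20. The passing probes thus do not speak for the list as a whole. None of the 8 photosynthesis probes, 5 petal probes, 4 seed and embryo probes, 3 flavonoid probes and 3 reference gene probes passed, and no set test of these lists did. The photosynthesis list had a camera adjusted p of 0.00542 without set 1 (adjusted p = 0.387 with an estimated correlation), against 0.409 with all arrays. With the labelled channels its adjusted p was 0.00298 without set 2 (adjusted p = 0.646 with an estimated correlation), against 0.508 with all arrays. SWEET9, the nectary sugar transporter, had -0.76 ± 0.62, CLV3, the stem cell peptide of the shoot meristem, 0.29 ± 0.14, UGT74B1, a glucosinolate enzyme, -0.56 ± 0.31, and BCAT4 of methionine chain elongation 0.11 ± 0.17 (SE, n = 4), none of which passed. No jasmonate or cell cycle gene had a probe that lists it.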

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

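The tests of the 3 patterns weighed in this part were all chosen after the results they bear on had been seen. Of 49 sets of 4 array values examined, 4 had 1 array far from the other 3 by Dixon's ratio at its 95% critical value, and chance flags about 1 in 20. AT1G35490 had -1.52 on set 2 (with sets 2 and 3 turned) against -2.95 to -2.73 on the others. AT5G62750 had -1.13 on set 2 against -3.004 to -2.842. AT5G12930 had 0.865 on set 4 against 0.993 to 1.01. SBPASE, a Calvin cycle enzyme, had 0.444 on set 1 against -0.422 to -0.299 with the same sets turned. Its deposited ratios were 0.444, 0.299, 0.422 and -0.355 on sets 1 to 4, so which array stands apart depends on the turning.

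The first pattern is that sets 1 and 4 ran opposite to sets 2 and 3. A constant dye bias would make sets of the same labelled channel correlate above 0, but the higher of those 2 correlations was -0.119, with its interval below 0. An exchange of the channels, or of the ratio's direction, for sets 3 and 4 needs the fixed pollen list on opposite sides in the pairs. Of its 15 complete probes 93.3% did lie so. Of its 17 probes 8 passed with sets 2 and 3 turned, so the list carries the pattern itself and could hardly lie otherwise. Its position is thus no separate evidence for an exchange. A real opposite difference between the RNA of the pairs predicts opposite sides too. Since 0 label fields part the pairs, it cannot be told apart from an exchange of channels in either pair. An inverted ratio would move values from the upper limit to the lower one, if they arose before the inversion. On sets 3 and 4, 698 and 683 gene probes sat at the upper limit and 8 and 9 at the lower. That argues against an inverted ratio there only under this condition, and when the limit was set is not known. Of the 8 sign patterns of the arrays, turning sets 2 and 3 alone called 528 probes, and the highest other count was 0. That is 1 of 8 patterns, and for the labelled orientation, with its count of 0, 8 of 8; 8 patterns are too few for a share under 0.05.

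The second pattern is the pile of values at the upper limit of the scale. Spots without signal may account for it: empty spots sat there at least 25.8 times as often as gene probes on each array. True differences beyond the scale would change sign between arrays of opposite channels, and 0.368% of the probes at a limit on all 4 arrays did so. The authors' rule for such spots is not given in the sources used here, so whether they filled in the limit or measured it stays open.

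The third pattern is that anther and pollen probes differed between the pairs. The anther probes had a median of -1.36 in sets 1 and 2 and 0.0464 in sets 3 and 4 (channels exchanged), and the pollen probes -1.45 and -2.15. Taken per probe with those channels exchanged, the difference between the pairs had a median of -1.32 for anther and 0.33 for pollen probes. These differ by -1.65 (11 and 15 probes, two-sided permutation p = 0.00043). After scale normalization the medians still had opposite signs (-1.30 and 0.40, permutation p = 0.00048), which argues against a difference of scale between arrays. The permutation takes probes as units. Several probes share a gene, so they are not independent, and the p-values do not measure the spread between pairs of arrays. With the labelled channels the values of sets 3 and 4 change sign, and the difference between the lists was not computed. Flowers of another stage in one pair may give such a pattern, as a hypothesis that stays untested, since 0 label fields give a stage.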

How the results depend on the processing

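The orientation with sets 2 and 3 turned, with all its settings, and the fits with limit values kept were chosen after the data had been seen. With the labelled channels the limma count of passing probes was 0 under all 13 alternative settings, including 0 to 0 when 1 array was left out, with 477 to 1780 probes at an unadjusted p under 0.05, and 0 with the limit values kept (1548 at an unadjusted p under 0.05). With the limit values kept and no array turned, as the fixed rule read literally would have it, 334 probes passed, of which 271 sat at the limit on all 4 arrays. With sets 2 and 3 turned the count was 528. In that orientation the total over both sides stayed within 1.5 times of 528 with a channel term (352, of which 320 were shared), median centring (539), scale normalization (569), complete values only (585), a size threshold (466), robust moderation (515) and array weights (527). It was 0 without moderation (2941 at an unadjusted p under 0.05), 0 with sets averaged to 2 replicates (1934), 158 with limit values kept, and 94 to 441 when 1 array was left out (94, 441, 117 and 116 without sets 1, 2, 3 and 4). The negative share was 89.0%, and 89.2% and 88.2% after centring and scaling. None of the 24 named genes reversed under any alternative of that orientation. The naming rule's demand for 1 sign on all 4 arrays largely fixed this in advance. All 24 lost their call without moderation and with averaged sets, 11 with a channel term, 1 each with robust moderation and array weights, and 22, 8, 23 and 21 without sets 1, 2, 3 and 4. Fewer arrays in these fits give fewer degrees of freedom; for the other settings the cause was not tested. Of the list tests under alternative settings 126 kept their side of the threshold, 10 lost their call and 8 gained one, and the calls of all lists were lost with an estimated correlation. The signal over background behind each ratio is unknown, which limits what dim probes can show.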

Other observations

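All tests in this part were chosen after the data had been seen. A small group of probes followed the labelled channels with large values: 15 were beyond 1 in size on all 4 arrays, 13 negative and 2 positive, with mean log2 ratios in the labelled orientation of 1.24 to 2.51 in size. None passed (lowest limma adjusted p 0.258). The 5 of them with 1 gene, named after their values were seen, were AT3G48460 (-1.88 ± 0.16), AT3G02480 (-1.85 ± 0.21), LTI30, a dehydrin induced by cold (-1.66 ± 0.19), AT4G04460 (-1.51 ± 0.19) and PAP20, a purple acid phosphatase (-1.24 ± 0.13; all SE, n = 4). With sets 2 and 3 turned the same genes had means between -0.27 and 0.24, which their choice by the labelled pattern largely fixed in advance. The unnamed probe with the largest value had 2.51 ± 0.16 (SE, n = 4).

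Gene families read from symbols did not separate with sets 2 and 3 turned. Of 46 families with at least 5 tested probes, none passed a one-sided Fisher's exact test for negative or positive calls against the 1407 probes with a family name. The cation/proton exchangers of the CHX family came nearest, with 2 of 7 probes on the negative side (Fisher's exact p = 0.00603, adjusted p = 0.277), chx28, named after its value was seen, among them at -1.31 ± 0.16 (SE, n = 4, limma adjusted p = 0.0211). The serine carboxypeptidase-like family had 3 of 28 probes (Fisher's exact p = 0.0121, adjusted p = 0.278).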
